A study of Mus musculus with 6 samples.

How the data were processed

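RNA sequencing of E0771 cells, a mouse mammary carcinoma line, was analysed in 6 libraries of 3 groups with 2 libraries each. The groups were cells carrying a control vector (Vector), cells expressing wild-type Malt1 (Malt1_WT) and cells expressing a Malt1 form that the labels call the PD mutant (Malt1_PD), an abbreviation that they do not spell out. Per the labels' protocols, each population was cultured with activated CD8 T cells at an effector-to-target ratio of 3 for 12 hours, washed, detached with trypsin and seeded again, and was lysed 6 hours later. Directional libraries were made from total RNA and read in pairs of 150 bases, per the labels' protocols. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

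The deposited table holds whole-number counts per gene, not normalised, for 28063 genes, of which 16389 are protein-coding. Trim Galore 0.6.0, STAR 2.7.3a and featureCounts 1.6.3 with genome build GRCm38.p6 are named in the submitters' processing notes. The strand setting of the counting and the version of the gene annotation are not given in the sources used here, so genes that overlap on either strand, near-identical copies such as the guanylate-binding and histone genes, and the overlapping mt-Nd4l and mt-Nd4 are less certain than other genes. No gene in the table has a total below 1 count. The same table holds log2 RPKM columns that the authors deposited beside the counts. The pair of these columns that carry the names of the Malt1_PD libraries could be recomputed from the deposited counts and gene lengths with edgeR (TMM factors, prior count 1) for all 28063 genes within 1e-06, and 4 further columns with repeated names were not used here. All tests used the counts. A spreadsheet had turned 25 gene symbols into dates, and these were restored from the gene identifiers. Of the 28063 identifiers, 28056 matched GENCODE release M21 (build GRCm38) without their version and 97.5% with it, and gene coordinates come from that release.

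The libraries held between 14045390 and 19962014 counts, so 3 counts, taken as the floor for a gene, equal 0.150 to 0.214 CPM (counts scaled to library size). This floor covers counting error only. Genes were kept by edgeR's filterByExpr by group, which left 14675 genes. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit and glmQLFTest), with a mean per group, all 6 libraries in 1 fit and no covariate. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F. CPM use TMM factors, and means are given with their SD over 2 libraries. The common dispersion was 0.0101, a coefficient of variation of 10.1%, with 3 residual degrees of freedom.

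Gene lists and the rule for naming genes were fixed before the data were examined. The 23 lists covered MALT1 partners and substrates, NF-kB target genes, Regnase-1 and Roquin target mRNAs, interferon-gamma response genes, type I interferon-stimulated genes, MHC class I and class II antigen presentation, immune checkpoint ligands, chemokines and cytokines, apoptosis and death receptor genes, immediate early and AP-1 genes, the unfolded protein and integrated stress response, hypoxia and glycolysis, cell proliferation, epithelial, mesenchymal and matrix genes, cholesterol synthesis, p53 targets, oxidative stress (NRF2) genes, T cell, B cell and myeloid markers, mitochondrially encoded mRNAs and replication-dependent histone mRNAs. Lists with at least 3 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over the 22 lists tested. The B cell list had 1 measured member and was not tested. By the rule, Malt1 and Cd274 were named in every comparison, then up to 8 called genes with the highest and 8 with the lowest log2 fold change (mean log2 CPM of at least 1, no overlap between the libraries of the groups, no predicted symbol), then up to 3 members of each list with the smallest p, called or not. Not every member picked in this way is reported here.

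Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, DESeq2 1.42.0 (Wald test), a fit of the 2 groups compared, the replicate number as a block, leaving out each library, a log2 fold change of at least 1 in size, leaving out immune marker genes, camera with an estimated correlation, fry, and adjustment over each list alone. The estimated correlation was below the preset for cholesterol synthesis (-0.04), Regnase-1 and Roquin targets (-0.05), type I interferon-stimulated genes (-0.01) and immediate early genes (-0.04). For these lists, correlation between members does not account for a higher p in that setting. With an estimated correlation, camera takes p from a t distribution with the 3 residual degrees of freedom, which raises small p-values. A list not called in that setting is therefore not shown to be unmoved. It was above the preset for others, such as the myeloid markers (0.45) and mitochondrially encoded mRNAs (0.38). The removal of each library's gene length trend (lowess, span 0.3, entered as offsets), a fit without Vector replicate 1 and Malt1_WT replicate 1, limma-voom, and list tests with Cd274 left out of the lists that hold it were chosen after seeing the data. With groups of 2, no other split of the libraries was tested. The log2 fold change of at least 1 filtered the main calls without a new test. Scripts were tested on simulated counts for Malt1_WT against Vector over 14675 genes with 200 changed genes. edgeR recovered 44% of genes changed 1.5-fold, 72% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold, with 14 calls among the 14168 unchanged genes that passed the filter. This simulation gave all groups the same spread, drew genes independently and held no length trend. In the data, the replicate difference had an SD of 0.296 log2 units in Vector against 0.138 in Malt1_PD, so these rates may not hold there. In a simulated list test, the list moved 1.5-fold was called with a preset and with an estimated correlation, and 0 of 20 unmoved lists were called with the preset. The simulated genes were drawn independently, while estimated correlations reached 0.47 in the measured lists (MHC class I). This test therefore cannot show how often the preset calls unmoved lists of correlated genes.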

Results

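E0771 mammary carcinoma cells carrying a control vector, wild-type Malt1 or the PD form of Malt1 were profiled by RNA sequencing after contact with activated CD8 T cells, with 2 libraries for each of the 3 populations. MALT1 is a scaffold and protease of the CARD-BCL10-MALT1 complex, which activates NF-kB and cleaves regulators such as A20, CYLD, Regnase-1 and Roquin. Total counts were 17929408 and 17994769 in the Vector libraries, 14045390 and 19962014 in Malt1_WT, and 15815122 and 16746124 in Malt1_PD. Between 21239 and 22483 genes had at least 1 count in a library. Mitochondrially encoded mRNAs took between 1.80% and 2.03% of the counts of a library. Few transcripts of T cells were counted. Summed over the 7 genes with a row of counts among 9 looked for (T cell receptor, CD3, CD8 and Ptprc transcripts), they came to 10 and 6 counts in the Vector libraries, 3 and 16 in Malt1_WT, and 5 and 9 in Malt1_PD, at most 0.798 CPM. The 3 listed T cell markers that passed the filter, which are not in this sum, had Vector means of 2.30 CPM (Coro1a), 1.88 CPM (Lck) and 0.561 CPM (Lag3).

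The libraries of a group differed from each other by more than sampling noise, with a chi-square per degree of freedom of 23.7 in Vector, 7.90 in Malt1_WT and 7.17 in Malt1_PD. Across the 9594 genes of a mean log2 CPM of at least 3, the difference between replicate 1 and replicate 2 had an SD of 0.296 log2 units in Vector, 0.183 in Malt1_WT and 0.138 in Malt1_PD. It followed gene length in Vector (Spearman rho across genes, which are not independent replicates, of -0.67) and in Malt1_WT (-0.53), with rho at 0.05 in Malt1_PD. The 961 longest of these genes, of 10129 nt or more, took 9.80% of the counts in Vector replicate 1 against 12.8% in replicate 2, and 11.05% against 12.6% in Malt1_WT. In Malt1_PD the shares were 12.2% and 12.1%. Transcripts resembling ribosomal RNA (Gm23935, CT010467.1, Lars2, Gm15564 and Mir6236, chosen after their values were seen) took 0.623% of the counts of Malt1_PD replicate 1 and between 0.0839% and 0.211% in the other libraries.

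**Figure D1:**
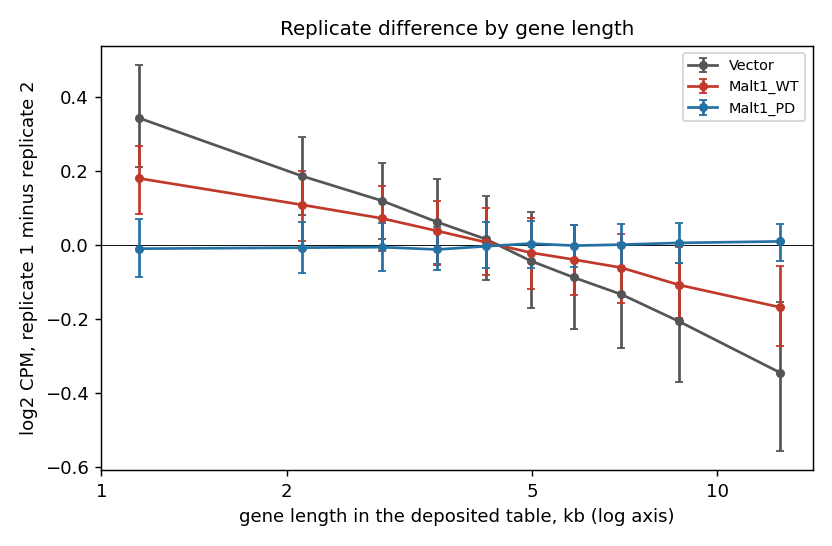
Difference in log2 CPM between replicate 1 and replicate 2 (vertical axis) by gene length in kb on a log axis, with the median and quartiles of bins of about 960 genes for each group. In Vector the medians go from 0.34 in the bin of shortest genes to -0.35 in the bin of longest genes, while those of Malt1_PD stay close to 0.

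Malt1 (ENSMUSG00000032688.8, chromosome 18, 65430938 to 65479067 in GRCm38), the gene expressed in the engineered cells, was counted in every library. It stood at 23.8 and 31.3 CPM in the Vector libraries, 67.2 and 82.1 CPM in Malt1_WT, and 106 and 95.7 CPM in Malt1_PD. The means were 27.6 ± 5.31, 74.7 ± 10.6 and 101 ± 6.92 CPM (SD, n = 2 each). At 11735 nt, Malt1 is among the genes of 10129 nt or more that took a lower share in Vector replicate 1 and Malt1_WT replicate 1. The lower Malt1 value of each of those groups was in that library. All 4 libraries of cells with added Malt1 thus lay above both Vector libraries, in the direction of the labels. A count per gene does not separate the cell's own Malt1 mRNA from that of a construct, nor the PD form from the wild type.

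**Figure D2:**
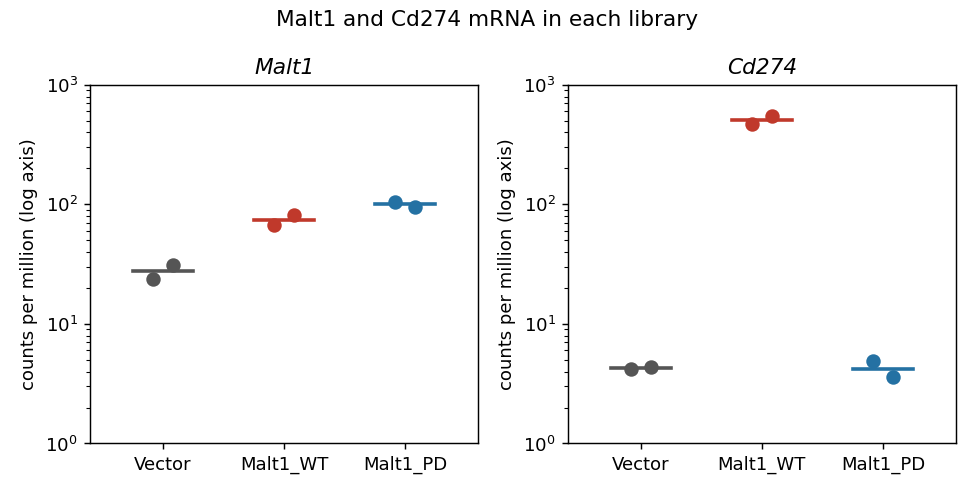
CPM of Malt1 (left) and Cd274 (right) on log axes, with a point for each library and a line at the mean of 2 libraries. Cd274 stands at 469 and 545 CPM in the Malt1_WT libraries and between 3.57 and 4.87 CPM in the other libraries.

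Malt1_WT cells were compared with Vector cells. Each form was a population of its own, so an effect of added Malt1 cannot be told apart from another difference between populations. Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095 in GRCm38), which encodes PD-L1, the ligand of the inhibitory T cell receptor PD-1, rose 118-fold. It went from 4.30 ± 0.104 CPM in Vector to 507 ± 54.0 CPM in Malt1_WT (SD, n = 2 each), a log2 fold change of 6.88 ± 0.16 (SE). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 1.24e-06, and it was past the threshold under all 16 alternatives, with a highest adjusted p of 2.85e-05. Malt1 itself had a log2 fold change of 1.44 ± 0.15 and an edgeR adjusted p of 0.0920 after Benjamini-Hochberg adjustment. Its adjusted p ranged from 2.9e-65 to 0.621 over the alternatives, of which 7 of 16 put it past the threshold, among them DESeq2 (1.45, adjusted p = 1.13e-13), the fit with the length trend removed (1.41, adjusted p = 9.88e-05), and the fits without Vector replicate 1 (0.000959) or without Vector replicate 2 (3.87e-05), which drop the spread of the Vector pair.

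Cd274 was the gene called higher among 14675, and 0 were called lower by edgeR, while 484 genes lay higher and 557 lower at an unadjusted p under 0.05. Together these were 1041 genes, above the share of 0.05 of those tested that unchanged genes give on average. Genes share the noise of the Vector pair, the widest in spread, so this excess is not read as a count of changed genes. DESeq2 called 14 higher and 17 lower, and limma-voom 1 and 0. The counts changed with the libraries in the fit. Without Vector replicate 1, edgeR called 19 higher and 31 lower, without Vector replicate 2 it called 468 and 131, and without Vector replicate 1 and Malt1_WT replicate 1, the libraries low on long genes, it called 434 and 502. The last fit sets single libraries against each other and takes its spread from the Malt1_PD pair alone, the pair with the narrowest spread.

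In the groups of immune genes, Cd274 stood apart from its companions in Malt1_WT against Vector. Of 22 measured interferon-gamma response genes, 1 rose (Cd274), and among the others Cxcl10, a T cell chemokine, had a log2 fold change of -0.37 ± 0.14 and Gbp6, a guanylate-binding protein gene with near-identical copies, 0.56 ± 0.25. The median of that list was -0.01 and its mean 0.34, opposite in sign, and camera pointed higher without calling it (adjusted p = 0.791), and lower without Cd274 (adjusted p = 0.713). Of 12 immune checkpoint ligands, 1 rose (Cd274). Nectin2, a ligand of TIGIT, stood at -0.23 ± 0.08 and Cd276, which encodes B7-H3, at 0.26 ± 0.10, and without Cd274 the 11 other members had a median of 0.06 and lay between -0.39 and 0.26 (camera for the whole list, adjusted p = 0.651). The 28 type I interferon-stimulated genes had a median of -0.05 (adjusted p = 0.392), with Cmpk2 at 0.53 ± 0.10, Rtp4 at -0.33 ± 0.11 and Oas3 at -0.29 ± 0.10. The 18 genes of MHC class I antigen presentation had a median of -0.02 (adjusted p = 0.817), with the class I gene H2-M3 at -0.43 ± 0.16 and the peptide-trimming enzyme gene Erap1 at 0.22 ± 0.09. The 5 measured class II genes had a median of -0.08 (adjusted p = 0.662), with the invariant chain gene Cd74 at -0.32 ± 0.30.

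In Malt1_WT against Vector, the 14 measured Regnase-1 and Roquin target mRNAs, which those RNA-binding proteins destabilise, had a median log2 fold change of -0.15, with 10 members below 0. Camera called the list lower (adjusted p = 0.0308, but adjusted p = 0.613 with an estimated correlation). Its members Il6 and Cxcl2, an inflammatory cytokine and a neutrophil chemokine, stood at -0.78 ± 0.15 (19.9 against 34.1 CPM) and -1.13 ± 0.22 (6.01 against 13.1 CPM), and Lcn2, which encodes lipocalin 2, at -0.24 ± 0.08. None of these 3 passed edgeR's threshold over all genes. The 24 chemokines and cytokines had a median of -0.15 (adjusted p = 0.392), with Csf3, the gene of the granulocyte colony-stimulating factor, at -0.74 ± 0.13. The 28 NF-kB target genes had a median of -0.05 (adjusted p = 0.325). The 22 MALT1 partners and substrates, Malt1 included, had a median of 0.03 (adjusted p = 0.443), with Casp8 at -0.23 ± 0.10. The 4 measured myeloid markers had a median of -0.34 and were called lower (adjusted p = 0.0171, but adjusted p = 0.691 with an estimated correlation), with the calprotectin subunit gene S100a8 at -0.66 ± 0.16.

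Among metabolic and growth genes in Malt1_WT against Vector, the 22 cholesterol synthesis genes had a median of -0.10, with 19 members below 0, and camera called them lower (adjusted p = 0.0169, but adjusted p = 0.613 with an estimated correlation). Pmvk, a mevalonate pathway kinase gene, stood at -0.39 ± 0.13, Hmgcs1 at -0.20 ± 0.09 and Insig1 at -0.19 ± 0.08. The 25 hypoxia and glycolysis genes had a median of 0.05 (adjusted p = 0.325), with the prolyl hydroxylase gene Egln3 at 0.27 ± 0.07 and Adm at 0.28 ± 0.10. The 25 cell proliferation genes had a median of -0.03 (adjusted p = 0.662), with Tyms at -0.17 ± 0.10 and Bub1 at -0.11 ± 0.08. The 23 immediate early and AP-1 genes had a median of -0.11 (adjusted p = 0.325), with Klf4 at 0.53 ± 0.09 and the ERK phosphatase gene Dusp6 at -0.42 ± 0.08. Of the 24 epithelial, mesenchymal and matrix genes (median 0.03, adjusted p = 0.662), Mmp3, which encodes stromelysin-1, stood at 9.07 against 22.2 CPM (-1.30 ± 0.15), Col1a1 at 58.1 against 33.7 CPM (0.79 ± 0.11) and Tgfbi at 195 against 134 CPM (0.54 ± 0.08).

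The other lists in this comparison were not called by camera. The 29 apoptosis and death receptor genes had a median of -0.02 (adjusted p = 0.912), with the necroptosis kinase gene Ripk3 at 0.42 ± 0.10. The 24 genes of the unfolded protein and integrated stress response had a median of -0.04 (adjusted p = 0.392), with Chac1 at -0.45 ± 0.13 and Sdf2l1 at -0.39 ± 0.11. The 18 p53 targets had a median of -0.02 (adjusted p = 0.495), with Gdf15 at -0.72 ± 0.14, and the 21 NRF2 genes a median of 0.02 (adjusted p = 0.495), with Ephx1 at 0.42 ± 0.10. The 13 mitochondrially encoded mRNAs had a median of 0.00 and a mean of 0.03, while the test pointed lower (adjusted p = 0.945), with mt-Co1 at -0.22 ± 0.05. The 13 histone mRNAs had a median of -0.18 (adjusted p = 0.392), with Hist1h1c at -0.26 ± 0.13. The 3 measured T cell markers had a median of -0.33 (adjusted p = 0.392), with Lck at -0.51 ± 0.30 and 1.31 against 1.88 CPM. The B cell list had 1 measured member, Pax5, at -0.04 ± 0.19. Camera's count of 3 called lists fell to 0 without Vector replicate 1, Malt1_WT replicate 1 or Malt1_WT replicate 2, and to 1 without Vector replicate 2. Across all lists, 1 gene passed edgeR's threshold over all genes, and 19 passed when adjusted over the list alone.

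**Figure D3:**
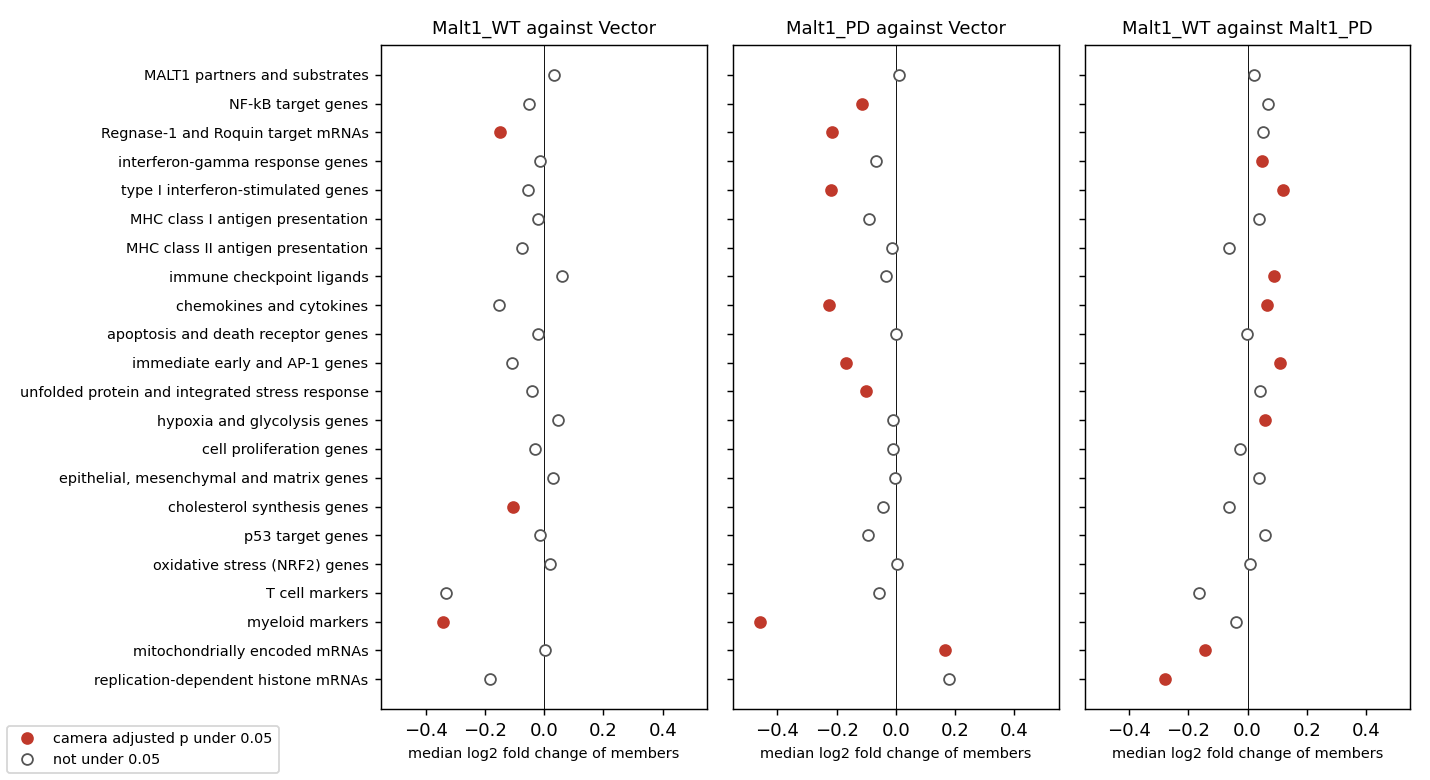
Median log2 fold change of the measured members (horizontal axis) of the 22 lists tested, in each of the 3 comparisons, with filled points where camera with a preset correlation gave an adjusted p under 0.05. Camera called 3, 8 and 8 lists from left to right, and 0 in each comparison with an estimated correlation. That setting rests on 3 residual degrees of freedom, so few lists can pass it.

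Malt1_PD cells were compared with Vector cells, with the same limit that form and population coincide. Malt1 rose 3.65-fold, from 27.6 ± 5.31 to 101 ± 6.92 CPM (SD, n = 2 each), a log2 fold change of 1.87 ± 0.15 (SE) with an edgeR adjusted p of 0.0265 after Benjamini-Hochberg adjustment. Cd274 stood at 4.22 ± 0.923 CPM against 4.30 ± 0.104 CPM in Vector, a log2 fold change of -0.03 ± 0.18 (edgeR, Benjamini-Hochberg adjusted p of 0.977). The Malt1 call was lost without Malt1_PD replicate 1 (1.79 ± 0.19, adjusted p = 0.598) or Malt1_PD replicate 2 (1.94 ± 0.20, adjusted p = 0.240), fits that leave that group a single library, while 14 of 16 alternatives kept it past the threshold, with adjusted p between 2.1e-119 and 0.598 over them all.

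Malt1 was the gene called higher in Malt1_PD against Vector, and 0 genes were called lower by edgeR, while 548 lay higher and 716 lower at an unadjusted p under 0.05. Together these were 1264 genes, above the share of 0.05 of the 14675 tested that unchanged genes give on average. As the same Vector pair is used, this excess is not read as a count of changed genes either. DESeq2 called 20 higher and 23 lower, and limma-voom 1 and 0. Without Vector replicate 1, edgeR called 47 higher and 64 lower, without Vector replicate 2 it called 648 and 280, without Malt1_PD replicate 1 or replicate 2 it called 0 and 0, and without Vector replicate 1 and Malt1_WT replicate 1, with the spread of the Malt1_PD pair alone, it called 948 and 1132.

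In Malt1_PD against Vector, the 28 type I interferon-stimulated genes had a median log2 fold change of -0.22, with 21 members below 0, and were called lower by camera (adjusted p = 0.000641, but adjusted p = 0.221 with an estimated correlation). Among them the antiviral synthetase genes Oas1a and Oas3 stood at -0.42 ± 0.09 and -0.46 ± 0.10, and Cmpk2 at 0.44 ± 0.10. The 14 Regnase-1 and Roquin target mRNAs had a median of -0.22 (adjusted p = 0.00369, but adjusted p = 0.252 with an estimated correlation), with Il6 at 15.3 against 34.1 CPM (-1.15 ± 0.15) and Ptgs2, which encodes cyclooxygenase-2, at 3.55 against 7.75 CPM (-1.12 ± 0.24). The 24 chemokines and cytokines had a median of -0.22 (adjusted p = 0.0132, but adjusted p = 0.290 with an estimated correlation), with Csf3 at 14.6 against 28.4 CPM (-0.96 ± 0.13) and Il33 at 0.978 against 3.17 CPM (-1.69 ± 0.32). The 28 NF-kB target genes had a median of -0.11 (adjusted p = 0.0101, but adjusted p = 0.290 with an estimated correlation), with Cxcl2 at -0.74 ± 0.21 and the NF-kB subunit gene Rel at -0.37 ± 0.13. The 4 myeloid markers had a median of -0.46 (adjusted p = 0.0157, but adjusted p = 0.398 with an estimated correlation), with Cd14 at -0.54 ± 0.16 and Cd68 at -0.57 ± 0.19. None of these named members passed edgeR's threshold over all genes.

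In Malt1_PD against Vector, the 23 immediate early and AP-1 genes had a median of -0.17, with 18 members below 0 (camera adjusted p = 0.000641, but adjusted p = 0.221 with an estimated correlation). Dusp6 and Spry2, feedback inhibitors of ERK signalling, stood at -0.63 ± 0.09 and -0.64 ± 0.12, and Klf4 at 0.41 ± 0.09. The 24 genes of the unfolded protein and integrated stress response had a median of -0.10 (adjusted p = 0.0498, but adjusted p = 0.696 with an estimated correlation), with Sdf2l1 at -0.41 ± 0.11 and Chac1 at -0.39 ± 0.13. The 13 mitochondrially encoded mRNAs had a median of 0.17 and were called higher (adjusted p = 0.0486, but adjusted p = 0.696 with an estimated correlation), with mt-Nd4l, which overlaps mt-Nd4, at 0.66 ± 0.12 and mt-Co3 at 0.32 ± 0.13. This comparison holds Malt1_PD replicate 1, the library with 0.623% of ribosomal RNA-like transcripts.

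The remaining lists were not called by camera in Malt1_PD against Vector, while fry called 1 of them, cholesterol synthesis, lower (fry adjusted p = 0.0331). The 22 interferon-gamma response genes had a median of -0.07 (adjusted p = 0.211), with Cxcl10 at -0.42 ± 0.14. The 12 checkpoint ligands had a median of -0.03 (adjusted p = 0.122), with Cd47 at -0.32 ± 0.08 and Pvr at -0.27 ± 0.08, and the 22 MALT1 partners and substrates a median of 0.01 (adjusted p = 0.560), with Bcl10 at -0.22 ± 0.10. Medians were -0.09 for MHC class I (adjusted p = 0.286), with Erap1 at 0.33 ± 0.09, and -0.01 for class II (adjusted p = 0.779), where the mean was 0.04 and the test pointed lower, with H2-DMb1 at -0.18 ± 0.15. The 24 epithelial, mesenchymal and matrix genes had a median and a mean below 0, of 0.00 and -0.01, while the test pointed higher (adjusted p = 0.928), with Mmp3 at 8.49 against 22.2 CPM (-1.39 ± 0.15), Col1a1 at 0.70 ± 0.11 and the gelatinase gene Mmp2 at 115 against 79.3 CPM (0.53 ± 0.09). Medians were 0.00 for apoptosis genes, above 0 with a mean and a test below it (adjusted p = 0.963), with Ripk3 at 0.35 ± 0.10, and -0.09 for p53 targets (adjusted p = 0.122), with Gdf15 at -0.77 ± 0.14 and Gadd45a at -0.49 ± 0.13. They were -0.01 for hypoxia and glycolysis (adjusted p = 0.753), with Ndrg1 at -0.28 ± 0.08, -0.01 for cell proliferation (adjusted p = 0.779), where the mean was 0.01 and the test pointed higher, with Mcm2 at 0.16 ± 0.08, and -0.04 for cholesterol synthesis (adjusted p = 0.188), with Insig1 at -0.21 ± 0.08. They were 0.00 for NRF2 genes (adjusted p = 0.779), with Ephx1 at 0.41 ± 0.10, and 0.18 for histone mRNAs (adjusted p = 0.473), with Hist1h1a at 0.87 ± 0.43. The 3 T cell markers had a median of -0.06 (adjusted p = 0.554), with Coro1a at -1.41 ± 0.47, and Pax5, the B cell marker measured, stood at 0.02 ± 0.19. Camera called 8 lists, but 3 without Vector replicate 1 and 5 without Malt1_WT replicate 1. Across all lists, 1 gene passed edgeR's threshold over all genes, and 28 passed when adjusted over the list alone.

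Malt1_WT cells were compared with Malt1_PD cells to set the 2 forms of Malt1 against each other. Cd274 was 120-fold higher with the wild type, at 507 ± 54.0 against 4.22 ± 0.923 CPM (SD, n = 2 each), a log2 fold change of 6.91 ± 0.16 (SE) with an edgeR adjusted p of 1.28e-06 after Benjamini-Hochberg adjustment. It stayed past the threshold under all 16 alternatives, with log2 fold changes between 6.70 and 7.15 and a highest adjusted p of 0.000175. Malt1 mRNA was at 74.7 ± 10.6 against 101 ± 6.92 CPM, a log2 fold change of -0.43 ± 0.14 that did not pass the threshold (edgeR, Benjamini-Hochberg adjusted p of 1.00). It passed under 1 of 16 alternatives, that without Vector replicate 1 and Malt1_WT replicate 1 (-0.29, adjusted p = 0.000131), a fit whose spread comes from the Malt1_PD pair alone, with adjusted p between 0.000131 and 1 over them all. Cd274 was the gene called higher, and 0 were called lower by edgeR, while 123 lay higher and 159 lower at an unadjusted p under 0.05. Together these were 282 genes, below the share of 0.05 of the 14675 tested that unchanged genes give on average. They are therefore read neither as a sign of further changes nor of their absence. DESeq2 and limma-voom each called 1 and 0, and without Vector replicate 1 and Malt1_WT replicate 1, with that spread, edgeR called 212 and 146.

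In Malt1_WT against Malt1_PD, the 28 type I interferon-stimulated genes had a median of 0.12, with 21 members above 0 (camera adjusted p = 0.00043, but adjusted p = 0.210 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, stood at 60.0 against 45.0 CPM (0.41 ± 0.08), Oas1a at 0.22 ± 0.09 and Oasl2 at 0.21 ± 0.09. The 22 interferon-gamma response genes had a median of 0.05 and a mean of 0.36, which holds Cd274 (adjusted p = 0.0292, but adjusted p = 0.296 with an estimated correlation). Without Cd274 the 21 others were not called by camera (adjusted p = 0.275). The 12 checkpoint ligands had a median of 0.09 (adjusted p = 0.00159, but adjusted p = 0.232 with an estimated correlation). Without Cd274 the 11 others were not called by camera (adjusted p = 0.104), while fry's mixed test, for changes in either direction, gave an adjusted p of 0.0491. These 11 lay between -0.19 and 0.27, among them Pvr, a ligand of TIGIT and CD226, at 0.27 ± 0.08 and Cd47, which encodes an anti-phagocytic surface protein, at 0.12 ± 0.08. The 24 chemokines and cytokines had a median of 0.07 (adjusted p = 0.00959, but adjusted p = 0.296 with an estimated correlation), with Il33 at 1.15 ± 0.34 (2.21 against 0.978 CPM) and Il34 at 0.40 ± 0.14.

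Between Malt1_WT and Malt1_PD, the 23 immediate early and AP-1 genes had a median of 0.11 (camera adjusted p = 0.00043, but adjusted p = 0.210 with an estimated correlation), with Dusp6 at 0.21 ± 0.09, Jun at 0.18 ± 0.08 and Dusp1 at 0.22 ± 0.11. The 25 hypoxia and glycolysis genes had a median of 0.06 (adjusted p = 0.00801, but adjusted p = 0.331 with an estimated correlation), with Egln3 at 0.20 ± 0.07 and Pdk1 at 0.17 ± 0.08. The 13 mitochondrially encoded mRNAs had a median of -0.14, with 12 members below 0 (adjusted p = 0.000919, but adjusted p = 0.450 with an estimated correlation), with mt-Cytb at -0.23 ± 0.07 and mt-Co1 at -0.14 ± 0.05. The 13 histone mRNAs had a median of -0.28 (adjusted p = 0.0171, but adjusted p = 0.488 with an estimated correlation), with Hist1h1a at 1.32 against 2.68 CPM (-1.03 ± 0.44). The type I interferon, chemokine, immediate early and mitochondrial lists were also called in Malt1_PD against Vector, in the opposite direction. These calls share the Malt1_PD libraries and are not separate evidence. The comparison of Malt1_WT with Malt1_PD also holds Malt1_PD replicate 1, with its 0.623% of ribosomal RNA-like transcripts. Camera called 8 lists here, and 5 without either Malt1_WT library or either Malt1_PD library.

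The other lists were not called by camera between Malt1_WT and Malt1_PD, while fry called 1 of them, cholesterol synthesis, lower (fry adjusted p = 0.0183). Medians were 0.02 for MALT1 partners and substrates (adjusted p = 0.962), where the mean was -0.01 and the test pointed higher, with Casp8 at -0.23 ± 0.10, 0.07 for NF-kB targets (adjusted p = 0.119), with Bcl3 at 0.18 ± 0.08, and 0.05 for Regnase-1 and Roquin targets (adjusted p = 0.314), with Ptgs2 at 0.64 ± 0.25 and Il6 at 0.37 ± 0.15. They were 0.04 for MHC class I (adjusted p = 0.362), with Tap1 at 0.13 ± 0.09, and -0.06 for class II (adjusted p = 0.852), with Cd74 at -0.31 ± 0.30. They were 0.00 for apoptosis genes (adjusted p = 0.962), 0.04 for the unfolded protein and integrated stress response (adjusted p = 0.247), with Dnajb9 at 0.22 ± 0.10, and -0.02 for cell proliferation (adjusted p = 0.275), with Mcm2 at -0.13 ± 0.08. They were 0.04 for epithelial, mesenchymal and matrix genes (adjusted p = 0.652), with Tgfbi at 0.16 ± 0.08, and -0.06 for cholesterol synthesis (adjusted p = 0.107), with Hsd17b7 at -0.30 ± 0.11 and Idi1 at -0.25 ± 0.10. They were 0.06 for p53 targets (adjusted p = 0.314), with Cdkn1a at 0.20 ± 0.10, and 0.01 for NRF2 genes (adjusted p = 0.545), with Gstm1 at 0.20 ± 0.13. Of the T cell markers, whose median was -0.16 and mean 0.15, with a test that pointed lower (adjusted p = 0.752), Coro1a stood at 1.08 ± 0.49 and Lck at -0.46 ± 0.31. Of the myeloid markers (median -0.04 and mean -0.03, with a test that pointed higher, adjusted p = 0.888), Cd68 stood at 0.37 ± 0.20. Pax5, the B cell marker measured, stood at -0.06 ± 0.19. Across all lists, 1 gene (Cd274) passed edgeR's threshold over all genes, and 2 (Cd274 and Rsad2) passed when adjusted over the list alone.

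The fold changes of both Malt1 populations against Vector were set against each other. Across 9592 genes the log2 fold changes of these comparisons had a correlation of 0.814 and a covariance of 0.0236, while 50 simulations of unchanged groups against shared controls, with 1 spread for all groups, gave a mean correlation of 0.497, a mean covariance of 0.0114 and a highest covariance of 0.0123. The Vector pair spread wider than the other pairs, and the covariance was 1.08 times the variance of the Vector mean estimated from that pair, and 1.91 times it with the length trend removed. The edgeR calls shared by both comparisons were 0, against an expected 6.81e-05 for independent lists, with up to 2 in 20 simulations. With DESeq2, 9 genes were called higher and 10 lower in both, Malt1 included, against 0.0191 and 0.0266 expected for independent lists. Part of the excess may come from the shared controls, or nearly all of it if the noise of the groups is independent. The Vector group has 2 libraries and cannot be split into parts that keep a replicate. The Malt1_WT changes against Vector and against Malt1_PD, which share the Malt1_WT libraries, had a correlation of 0.174 and a covariance of 0.00299, against simulated means of 0.499 and 0.0115. They shared 1 called gene, Cd274, against an expected 6.81e-05 for independent lists and up to 2 in 20 simulations of unchanged groups.

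**Figure D4:**
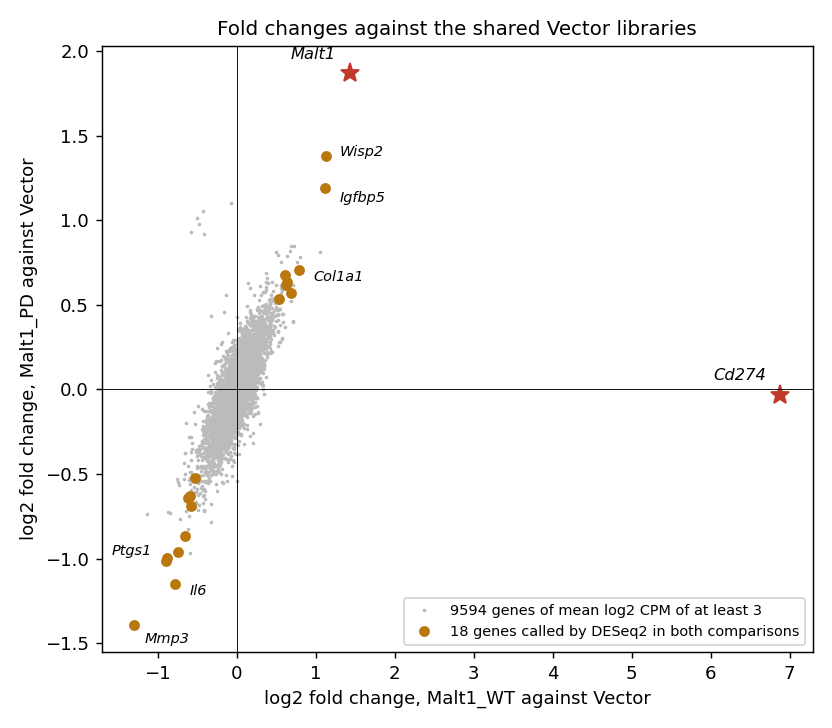
Log2 fold change of Malt1_PD against Vector (vertical axis) by that of Malt1_WT against Vector (horizontal axis) for 9594 genes, with Malt1 and Cd274 as stars and 18 genes called by DESeq2 in both comparisons as large points. Cd274 lies at 6.88 and -0.03, away from the diagonal band that holds most genes.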

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

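Of the tests in this part, that of a construct as the source of Cd274 mRNA was chosen only after the result was seen. The bounds of the other tests were set before those tests, but for a pattern of Cd274 high in both Malt1_WT libraries only. That pattern was thus already known when they were set.

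Cd274 stood out because its effect differed between the 2 forms of Malt1 measured against the same Vector libraries. The effect of Malt1_WT minus that of Malt1_PD was 6.91 ± 0.16 on the log2 scale (SE), which is the direct comparison of these groups, with an edgeR adjusted p of 1.28e-06 after Benjamini-Hochberg adjustment. Both Malt1_WT libraries held 469 and 545 CPM, and the other 4 between 3.57 and 4.87 CPM.

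The tables argue against 3 explanations of the high Cd274 counts in Malt1_WT. A general rise of the interferon-gamma response would raise the other response genes, but these 21 genes had a median log2 fold change of 0.0463 against Malt1_PD, and all 21 lay below 1. A gain of the chromosome segment would raise the neighbours of Cd274. The 21 tested genes within 2 Mb on either side had a median of 0.000367 against Malt1_PD, with 20 of 21 below 1. The exception to the bound set beforehand for every neighbour was Il33, at 1.15 ± 0.34 from 0.978 and 2.21 CPM. Against Vector, at 3.17 CPM, Il33 was lower in Malt1_WT (log2 fold change of -0.54). A loss of Regnase-1 or Roquin control that raises all listed targets about as much as Cd274 would raise the mRNAs of that list, which does not hold Cd274, but its 14 measured members, of 21 listed, had a median of 0.0514 and all lay below 1. A loss of control over Cd274 alone, or over few of these mRNAs, was not tested by this and stays open. A Cd274 sequence expressed from a construct could give the mean of 507 CPM and stays open. A count per gene does not show which exons were read. An effect of wild-type Malt1 on Cd274, which the groups name, stays open beside it. Since each form was a population of its own, that effect cannot be told apart from another difference between the populations.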

How the results depend on the processing

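Chosen only after the result was seen were the tests by limma-voom, of lists without Cd274, with the gene length trend removed and without the 2 libraries low on long genes (Vector replicate 1 and Malt1_WT replicate 1). Over the values of the named genes, 1956 kept their direction and their side of the threshold, 341 passed it newly, 2 no longer passed it and 9 changed sign. Cd274 stayed past it under all 16 alternatives in both comparisons that hold Malt1_WT, between 6.77 and 6.99 against Vector and between 6.70 and 7.15 against Malt1_PD. With 1 gene called per comparison in the main fit, keeping a side mostly meant staying uncalled. DESeq2 size factors, the fit of 2 groups and limma-voom left 1 gene higher and 0 lower in each comparison. So did a log2 fold change of at least 1, which filters the main calls without a new test and could not change them. No scaling moved the median of all genes by more than 0.01. For the changed values that follow, the cause was not tested unless named. With groups of 2, leaving out a library leaves a lone sample that is assumed to vary like the others, and leaving out either Vector library removes the spread of the Vector pair, the widest, from the fit. Without the 2 libraries, the spread comes from the Malt1_PD pair alone, the narrowest. Depth limits genes near 3 counts, 0.150 to 0.214 CPM.

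Genes called higher and lower in Malt1_WT against Vector numbered 52 and 61 with no low-count filter, 14 and 17 with DESeq2, 26 and 29 with the length trend removed, and 434 and 502 without the 2 libraries low on long genes. In Malt1_PD against Vector they numbered 94 and 94, 20 and 23, 30 and 57, and 948 and 1132 under the same alternatives. In Malt1_WT against Malt1_PD, 11 were lower with no filter, and 212 were higher and 146 lower without the 2 libraries. Leaving out each library in turn gave 1 to 468 higher and 0 to 131 lower in Malt1_WT against Vector, and 0 to 648 higher and 0 to 280 lower in Malt1_PD against Vector, with the highest counts without Vector replicate 2.

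Lists called in Malt1_WT against Vector, 3 at first, numbered 0 with no filter, 0 without the 2 libraries, 0 with an estimated correlation, 1 with fry and 14 with fry's mixed test. In Malt1_PD against Vector, 8 became 5 with no filter, 5 without immune marker genes, 2 without the 2 libraries, 0 with an estimated correlation, 4 with fry and 10 with fry's mixed test. In Malt1_WT against Malt1_PD, 8 became 5 with no filter, 4 without the 2 libraries, 0 with an estimated correlation, 4 with fry and 4 with fry's mixed test. With Cd274 left out of its lists, 3, 8 and 6 lists were called. Fry does not compare a list with other genes. With an estimated correlation, the 3 residual degrees of freedom raise small p-values, so 0 called lists does not show that none moved. Leaving out each library gave 0 to 3, 3 to 9 and 5 to 7 called lists in these comparisons.

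Signs changed for Pax5 in the 3 comparisons and Cd274 in Malt1_PD against Vector, all near 0 in the main fit. They also changed for Cd74 in Malt1_WT against Malt1_PD, at -0.31 ± 0.30 (SE) in that fit. Pax5 went to -0.25 in Malt1_PD against Vector and to 0.0239 in Malt1_WT against Malt1_PD without the 2 libraries. With each library left out, Pax5 ranged from -0.31 to 0.30 in Malt1_WT against Vector, from -0.25 to 0.36 in Malt1_PD against Vector and from -0.17 to 0.0233 in Malt1_WT against Malt1_PD, Cd274 from -0.27 to 0.18 in Malt1_PD against Vector, and Cd74 from -0.58 to 0.0301 in Malt1_WT against Malt1_PD.

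With the replicate block, 4 genes were higher and 2 lower in Malt1_WT against Vector, 3 and 6 in Malt1_PD against Vector, and 1 and 0 in Malt1_WT against Malt1_PD, and Malt1 passed in Malt1_WT against Vector (1.44 ± 0.13, adjusted p = 0.0111, within a range of 2.9e-65 to 0.621 over its alternatives). The labels tie libraries across groups by this number alone and do not say what it marks, and their deviations from the group means had a correlation across genes of 0.681 for Vector and Malt1_WT, -0.0097 for Vector and Malt1_PD and 0.0288 for Malt1_WT and Malt1_PD.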

Other observations

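Chosen only after the result was seen were the tests of explanations for the genes shared by both Malt1 populations and for the libraries that deviate together.

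Besides Malt1, DESeq2 called 18 genes in the same direction in both Malt1 populations against Vector, genes chosen after their values were seen and of which edgeR called 0 (Benjamini-Hochberg adjusted p between 0.0629 and 0.358 over both comparisons). Lower in both were Ptgs1, which encodes cyclooxygenase-1, at 86.0 and 84.0 CPM in Vector against 41.9 and 49.96 CPM in Malt1_WT and 41.9 and 43.1 CPM in Malt1_PD, and Mmp3, at a mean of 22.2 CPM in Vector against 9.07 and 8.49 CPM. The cytokine genes Il6 and Csf3 and the fatty acid-binding protein gene Fabp4 were also lower, Fabp4 at 233 CPM in Vector against 148 CPM in Malt1_WT and 128 CPM in Malt1_PD (DESeq2 log2 fold changes of -0.65 ± 0.15 and -0.86 ± 0.15), with Arhgap6, Upp1, Prph, Slc9a3r1 and Osbp2. Higher in both were the matrix and smooth muscle genes Col1a1 and Acta2, the complement gene C3, at 266 CPM in Vector against 408 and 425 CPM, and Igfbp5, an insulin-like growth factor-binding protein gene, at 13.4 CPM against 29.2 and 30.7 CPM, with Wisp2, Olfml3, Piwil2 and Tarbp1.

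For these 18 genes, the tables argue against the gene length trend between libraries, since their median log2 fold change was 0.69 in size before and after its removal (ratio 1.00), and against T cells left in the Vector libraries, since the summed T cell transcripts came to 0.563 CPM at most there while the median loss of the genes that were lower was 26.1 CPM. The 4 measured myeloid markers, among them S100a8, Cd14 and Cd68, had medians of -0.34 and -0.46 in Malt1_WT and Malt1_PD against Vector (camera adjusted p = 0.0171 and 0.0157, but adjusted p = 0.691 and 0.398 with an estimated correlation), with Lyz2, abundant in myeloid cells, at 2.61 CPM in Vector, 2.05 in Malt1_WT and 2.73 in Malt1_PD. Noise of the shared Vector libraries stays open and cannot be told apart from an effect of either Malt1 form or of the vectors. The covariance of the comparisons was 1.08 times the variance of the Vector mean (0.0236 against 0.0219). With the length trend removed it was 1.91 times that variance (0.0225 against 0.0118), on the other side of the bound of 1.5. The bound takes Vector noise as independent of the other groups, while the replicate differences of Vector and Malt1_WT correlated at 0.681. Noise shared by these groups would lower the covariance that noise alone gives, by an amount not estimated here. The ratio therefore does not decide. An earlier criterion was an observed covariance of 0.0236 above every simulated one (highest 0.0123). It would have excluded noise of the shared Vector libraries. It was replaced because the simulation gave all groups the same spread, while the Vector pair had the widest.

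Vector replicate 1 and Malt1_WT replicate 1 deviated together from their partner libraries, with a correlation of 0.681 across genes. The tables argue against a gene length trend as the whole cause, since the correlation was 0.512 after its removal, and against GC content, since Spearman's rho of the difference with GC was 0.0799 in Vector and -0.0126 in Malt1_WT. They also argue against a day or batch shared by all 3 replicate 1 libraries, since the higher correlation of the Malt1_PD difference with the others was 0.0288. A batch that held only these 2 libraries, or a difference in RNA integrity or library making, may be the cause and was not tested, and no biological explanation was tested.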
